A study of Hordeum vulgare with 15 samples.

How the data were processed

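Poly(A) RNA was measured in the scutellum of barley (Hordeum vulgare, cultivar Golden Promise) in 15 libraries, 3 from each of 5 groups. Per the labels, immature embryos (IME) came from seeds 14 days post-pollination and were taken before culture and after 24 h or 48 h of it, and mature embryos (ME) before culture and after 24 h. Per the labels' protocols, the libraries were strand-specific through dUTP marking, carried unique molecular identifiers in their adapters, and were sequenced as pairs on an Illumina NovaSeq. The labels do not say whether replicates came from separate plants, grain lots or cultures, so n counts libraries.

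The authors deposited a single table with 32968 loci, giving a raw count and an FPKM value for each library. The deposited counts are whole numbers with no exception (0 non-whole values) and total 56351687 to 70467725 per library. The deposited FPKM (fragments scaled by transcript length and library total) values are the authors' own, and what counts toward that total is not stated. HISAT, UMI-tools, StringTie and edgeR are named per the submitters' processing notes, with no versions, order or settings. The genome build and annotation are not given in the sources used here. The table gives coordinates for 14514 loci, and they are not used because no build is named. Of the identifiers, 18454 are loci named by the assembler (MSTRG) and have no coordinates, and 174 loci name several genes at once. None of the 29274 HORVU identifiers in the table matched the reference gene table (0 matches), so identifiers and names are those of the deposited table. Whether the deposited counts used strand is not stated, and reads of near-identical paralogs, such as histones, and of overlapping loci could be split between them.

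Names came from the description column for 3646 loci and, for 1131 more, from the KEGG orthology entry in the table, translated through a hand-written key. Together 4777 loci had an informative name. Before the data were examined, 39 gene lists of processes, hormones, seed products, regulators and stress responses were fixed as text patterns on descriptions. KEGG and Gene Ontology codes were added to the lists after the annotation columns had been read and before any test. The lists of heat shock proteins, glutathione S-transferases, WRKY factors, bHLH factors and pathogenesis-related proteins took every member from these codes. Codes also gave 78 of 79 members in the table for abscisic acid, 74 of 76 for oil bodies and 9 of 12 for LEA proteins. In the table, 6 lists had no member: endosperm storage hordeins, embryonic axis and meristem, embryogenesis and regeneration regulators, LBD proteins, growth-regulating factors, and MYB factors. A further list, NAC factors, had 3 tested members, under the minimum of 5, and was not tested. It is named below together with the 32 lists that were tested. The lists were histones, DNA replication, mitosis and cyclins, ribosomal proteins, ribosome biogenesis, auxin early response and conjugation, auxin response factors, auxin transport and synthesis, cytokinin, gibberellin, ethylene, abscisic acid, jasmonate, late embryogenesis abundant (LEA) proteins, oil bodies and seed storage globulins, amylase and protease inhibitors of the grain, photosynthesis, WRKY, NAC and bHLH factors, heat shock proteins, peroxidases, glutathione S-transferases, pathogenesis-related proteins, cell wall remodelling, cellulose synthases, glyoxylate cycle and beta-oxidation, glycolysis and fermentation, starch and amylases, flavonoid and phenylpropanoid synthesis, DNA methylation and Polycomb, proteasome, and sugar and amino acid transporters.

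The design fixed beforehand named limma on log2 FPKM, with edgeR to replace it if the table held counts. It did hold counts, so edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, TMM factors, robust fit, all 15 libraries in a single fit with group as the only term) became the main test. Loci with at least 1 FPKM in at least 3 libraries were tested, which left 20858. A gene is called higher or lower at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 change of at least 1, and "rose" and "fell" are used of called genes only. The 7 comparisons were IME at 24 h against 0 h, at 48 h against 24 h and at 48 h against 0 h, ME at 24 h against 0 h, IME against ME at 0 h and at 24 h, and the interaction, which is the 24 h change of IME minus that of ME. Standard errors are the log2 change divided by the square root of its F statistic. Group values are means of the deposited FPKM ± SD over 3 libraries. Where every library of a group had 0 counts, the fold is given as a lower bound computed from 3 counts over the whole group.

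Lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) on log2 CPM with a prior count of 2, adjusted by Benjamini-Hochberg over the 32 lists of a comparison, and again with an estimated correlation. List counts are given over all tested genes and also adjusted over the list alone. For camera the design had named log2(FPKM + 1). The rule for naming genes was fixed before the data were examined, with genes ranked by their change in log2(FPKM + 1). Once edgeR was the main test, genes were ranked by its log2 change instead, which can be far larger for loci near 0 in a group. The rule takes, per comparison, the 5 called genes with the largest rise and the 5 with the largest fall, with an informative name, at least 10 FPKM on average in the higher group, no overlap between the libraries of the compared groups, and 1 gene per description. For genes compared 3 against 3, chance alone gives such a separation in 10% of cases. It adds up to 2 called members of each called list, in the list's direction and with at least 5 FPKM. The interaction takes 5 genes in each direction without the overlap condition.

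The steps were tested on simulated counts drawn from the libraries' own means and spread. For IME at 24 h against 0 h (20858 genes), edgeR recovered 26% of genes changed 2-fold and 80% of those changed 4-fold as calls, with 3 unchanged genes called. For the interaction the shares were 15% and 68%, with 4 unchanged genes called. DESeq2 (1.42.0) recovered 42% at 2-fold for IME but called 41 unchanged genes. A 2-fold change lies at the limit of a call, so any estimate below it could not be called. By adjusted p alone, edgeR recovered 39% at 2-fold for IME and 17% for the interaction, and DESeq2 64% for IME. Camera called the simulated moved list and 0 of 31 unchanged lists. Genes were drawn independently there, so this does not test the preset correlation on genes that vary together.

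Alternatives planned before the data were examined were other scalings of the FPKM values (median of ratios, TMM, quantile), pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, adjusted p alone, limma without trend and robust, a fit on only the compared groups, a replicate block, camera with an estimated correlation, and leaving out each library in turn. DESeq2, limma on the deposited FPKM, scaling by library size alone, a fit that is not robust, lists from descriptions alone, lists of members above the median count, and tests without structural RNA loci or without a set of loci read in IME at 0 h alone were added after the table had been seen. Camera over KEGG and Gene Ontology terms was added at the same point. Loci read in IME at 0 h alone are those with a mean there of at least 5 FPKM and a many-fold lower mean, not always 0, in every other group. Nothing was left out of the 15 libraries.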

Results

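The libraries sampled the scutellum, the organ of the cereal embryo that lies against the endosperm, before and during culture on callus induction medium with the embryonic axis removed. Immature embryos (IME) were sampled before culture (0 h) and after 24 h or 48 h of it, and mature embryos (ME) before it and after 24 h, with 3 libraries per group. The study title names the search for factors that promote embryogenic callus. The replicates of IME before culture held 65422019, 65711616 and 65647330 counts, those at 24 h held 57981229, 62452115 and 66432960, and those at 48 h held 65762427, 70467725 and 68785368. The replicates of ME before culture held 56351687, 62278569 and 64257772 counts, and those at 24 h held 67790311, 70347555 and 68678205. Values below are mean FPKM ± SD with n = 3 libraries per group, and log2 changes carry standard errors (SE) from edgeR.

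Fresh and cultured scutella were far apart, and the embryo types were further apart before culture than after it. The first principal component held 47.1% of the variance and separated 0 h from cultured libraries, and the next held 31% and separated the embryo types. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.94 to 0.96 between replicates. The highest r to a library of another group was 0.703 for IME at 0 h and 0.699 for ME at 0 h, against 0.944 between IME at 24 h and 48 h. A single locus without an informative name, HORVU4Hr1G002800 (chosen after its values were seen), took 4.35% to 4.64% of the counts of the IME libraries at 0 h.

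**Figure D1:**
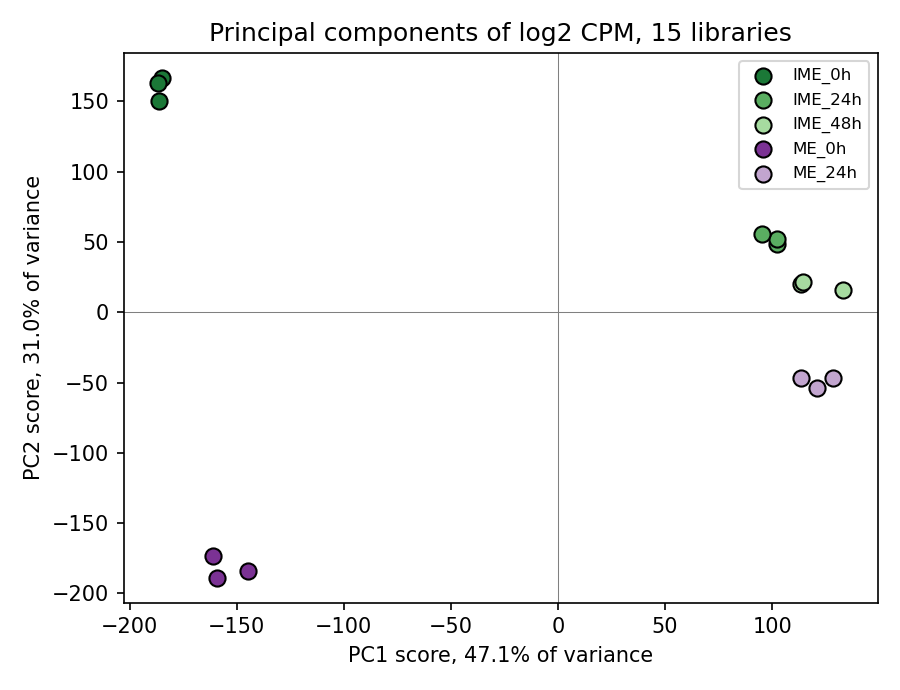
Principal components of log2 CPM over 20858 genes, with the first on the x axis (47.1% of variance) and the second on the y axis (31%); each point is a library, coloured by group. The 0 h libraries lie to the left, the cultured libraries to the right, and IME libraries above ME libraries of the same time.

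**Figure D2:**
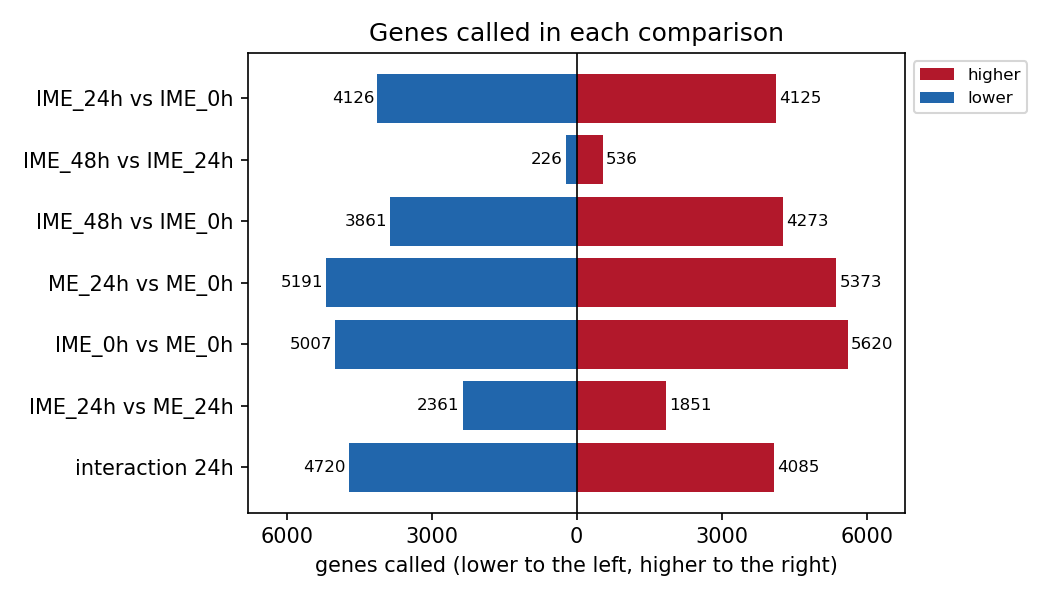
Number of genes called by edgeR in each of the 7 comparisons; bars to the right count genes higher and bars to the left genes lower in the group named first. The fewest calls, 536 higher and 226 lower, were between IME at 48 h and 24 h.

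The comparison of IME at 24 h with 0 h asked what the first day on the medium changed in immature scutella. At the preset correlation only, the lists of DNA replication, ribosomal proteins, auxin early response and peroxidases were called higher, and those of LEA proteins, oil bodies and heat shock proteins lower. Proliferating cell nuclear antigen (HORVU2Hr1G088030), the sliding clamp of DNA polymerase, rose from 10.1 ± 3.25 to 127 ± 20.9 FPKM (log2 change 3.19, SE 0.26). Ribonucleoside-diphosphate reductase (HORVU7Hr1G027430), which makes deoxyribonucleotides, rose from 12.7 ± 0.999 to 101 ± 3.08 FPKM (2.51, SE 0.19). An auxin-responsive protein (HORVU7Hr1G026970) was close to 0 at the start, with 0.0154 ± 0.0266 FPKM, and reached 39.5 ± 14.3 FPKM. Its log2 change was 10.06 to 14.03 with a library left out, and values of several other genes near 0 in a group also moved by more than 3 units. The small auxin-up RNA gene HORVU7Hr1G075080 went from 0.0474 ± 0.041 to 13.4 ± 0.409 FPKM. A peroxidase (HORVU2Hr1G018480) rose from 0.0859 ± 0.0427 to 145 ± 15.5 FPKM (10.19, SE 0.61). An endoglucanase (HORVU5Hr1G052830) had 0 counts in the 3 libraries at 0 h and 10.7 ± 2.43 FPKM at 24 h, at least 1096-fold higher. An rRNA N-glycosidase (HORVU4Hr1G087400), the class of enzyme that inactivates ribosomes, rose from 0.0061 ± 0.0106 to 11.5 ± 3.18 FPKM. A glutathione S-transferase (HORVU5Hr1G006330) rose from 0.0421 ± 0.0153 to 21.2 ± 1.75 FPKM (8.28, SE 0.30).

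Among the falls, an HSP70 chaperone (HORVU4Hr1G059260) went from 2589 ± 80.2 to 1.05 ± 0.886 FPKM (log2 change -11.71, SE 0.63). A small heat shock protein (HORVU6Hr1G038320) went from 116 ± 4.75 to 0.0389 ± 0.0674 FPKM (-11.85, SE 0.75). Glutamate decarboxylase (HORVU3Hr1G112860) fell from 241 ± 25.2 to 0.106 ± 0.168 FPKM, and a hexosyltransferase (HORVU4Hr1G052450) from 528 ± 33.9 to 0.312 ± 0.274 FPKM. The dehydrin HORVU6Hr1G084070 ("Deyhydrin 4" in the table), of a family that accumulates before desiccation, fell from 360 ± 36.5 to 2.04 ± 0.916 FPKM (-7.92, SE 0.41). Of 2 oleosins, which coat oil bodies, HORVU5Hr1G056030 fell from 2741 ± 139 to 69.5 ± 13.6 FPKM and HORVU4Hr1G005800 from 2809 ± 100 to 159 ± 47.0 FPKM. An ABRE-binding bZIP factor of abscisic acid signalling (HORVU3Hr1G083250) fell from 12.2 ± 0.753 to 0.101 ± 0.022 FPKM. An abscisic acid 8'-hydroxylase (HORVU5Hr1G068330), which degrades the hormone, fell from 19.8 ± 2.53 to 0.305 ± 0.0112 FPKM. A NAC factor (HORVU4Hr1G017430) fell from 84.8 ± 2.94 to 11.2 ± 0.94 FPKM, another (HORVU7Hr1G055080) rose from 0.585 ± 0.128 to 3.16 ± 0.492 FPKM (a call lost with a pseudocount of 5), and the remaining tested NAC factor was not called. The subtilisin-chymotrypsin inhibitor CI-1A (HORVU1Hr1G012130) went from 12.6 ± 9.45 FPKM to 0 counts, at least 308-fold lower, and its values at 0 h ran from 4.22 to 22.9 FPKM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, CI-1A had the highest adjusted p of the genes named for this comparison (0.0074).

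Of the tested lists, 12 were called by camera between IME at 24 h and 0 h, none of which held with an estimated correlation. Ribosomal proteins were higher (176 of 344 tested loci higher and 21 lower, median log2 change 1.04, camera adjusted p = 9.2e-13, and adjusted p = 0.22 with an estimated correlation), and their share of all counts went from 3.25% ± 0.144 to 9.42% ± 0.240. Ribosome biogenesis had 46 of 121 higher and 9 lower (median 0.68, adjusted p = 0.00012, and 0.34 with an estimated correlation). DNA replication had 28 of 79 higher and 5 lower (median 0.77, adjusted p = 0.00024, and 0.22 estimated), and histones 37 of 120 higher and 6 lower (median 0.75, adjusted p = 0.002, and 0.67 estimated). Auxin early response and conjugation genes (Aux/IAA, SAUR and GH3) had 34 of 50 higher and 3 lower, with a median of 1.91, or 1.87 with loci of a group at 0 counts set to their bound (adjusted p = 5.4e-05, and 0.12 estimated). Peroxidases had 44 of 79 higher and 8 lower (median 1.67, adjusted p = 0.00034, and 0.22 estimated). Glutathione S-transferases had 29 of 73 higher and 10 lower (median 0.91, adjusted p = 0.0043, and 0.22 estimated), a call lost with FPKM as deposited and with library size only, where the adjusted p reached 0.0757. The share of counts of this list went the other way, from 0.882% ± 0.137 to 0.684% ± 0.0198. Proteasome loci had 14 of 103 higher and 11 lower (median 0.37, adjusted p = 0.002, and 0.25 estimated).

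LEA proteins were lower, with 10 of 11 loci lower and 0 higher (median -7.35, camera adjusted p = 0.00012, and adjusted p = 0.12 with an estimated correlation). Heat shock proteins had 30 of 63 lower and 11 higher (median -0.96, adjusted p = 0.00012, and 0.12 estimated), and their share of counts went from 6.02% ± 0.0952 to 1.21% ± 0.00933. The abscisic acid list had 27 of 50 lower and 6 higher (median -1.12, adjusted p = 0.002, and 0.12 estimated). Oil bodies and seed storage globulins had 23 of 39 lower and 9 higher (median -4.56, or -4.58 at the bound, adjusted p = 0.002, and 0.34 estimated), and went from 8.69% ± 0.216 to 0.839% ± 0.227 of counts. Its members include 11 loci that were read in IME at 0 h alone and ranked its libraries in the order of the grain inhibitors, with spreads of 4.54-fold to 6.21-fold. Without these 11 the list had 12 of 28 lower and 9 higher (median -0.05, adjusted p = 0.322). Part of that change follows from the selection, since a locus read in IME at 0 h alone is a fall by definition. Every count of these 12 lists was identical when adjusted over the list alone.

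In total 4125 genes were higher and 4126 lower at 24 h. This even split depends on the scaling. The TMM factors were 0.827 to 0.847 for IME at 0 h and 1.14 to 1.17 for IME at 24 h. Scaling by library size only differs from the main fit in leaving these factors out. FPKM as deposited gave 4640 higher and 2352 lower (66.4% higher against 50.0%), and scaling by library size only gave 6472 and 2953 (68.7% higher). Those settings moved the median log2 change of all genes by 0.32 and 0.46, and the first also changed the test, the input values and the pseudocount.

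**Figure D3:**
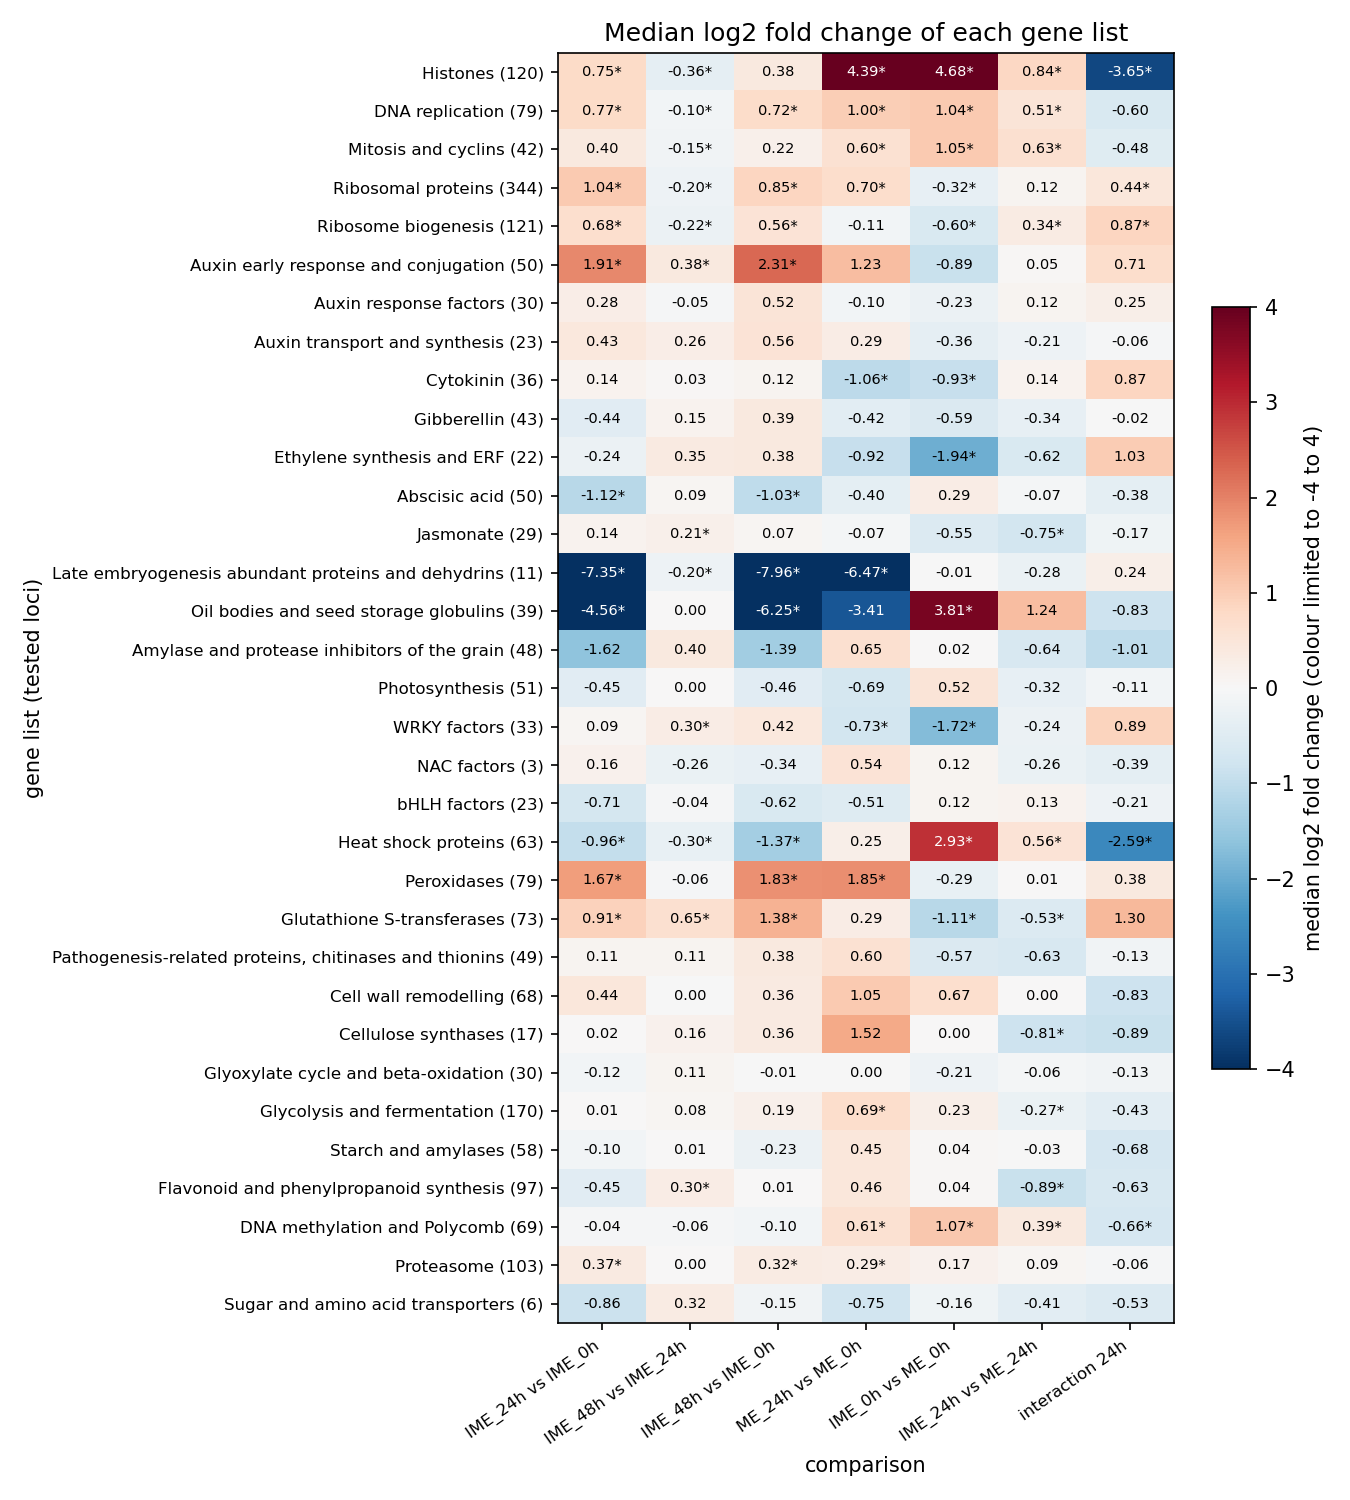
Median log2 change of each list with members (33, tested loci in brackets) in the 7 comparisons, printed in each cell and coloured up to 4 in either direction; asterisks mark a camera adjusted p under 0.05 at the preset correlation. LEA proteins have medians of -7.35 and -6.47 after 24 h of culture in IME and ME.

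Between 24 h and 48 h, immature scutella had fewer called genes than any other comparison. Lists of glutathione S-transferases and of flavonoid and phenylpropanoid synthesis were called higher and those of heat shock proteins and histones lower, and of these only the first held with an estimated correlation. A glutathione S-transferase (HORVU3Hr1G095730) rose from 1.28 ± 0.116 to 16.8 ± 8.80 FPKM (log2 change 3.70, SE 0.50), and another (HORVU2Hr1G124300) from 1.48 ± 0.413 to 10.1 ± 1.80 FPKM (2.76, SE 0.36). A peroxidase (HORVU7Hr1G108210) went from 0.147 ± 0.155 to 13.4 ± 10.5 FPKM (6.41, SE 0.76), and a potassium transporter (HORVU3Hr1G096860) from 2.99 ± 0.268 to 20.1 ± 1.97 FPKM. A flavonol synthase (HORVU4Hr1G080610) rose from 0.674 ± 0.367 to 8.60 ± 2.56 FPKM, and a SAUR gene (HORVU5Hr1G062580) from 2.65 ± 0.390 to 7.03 ± 0.606 FPKM. Small heat shock proteins fell further, HORVU3Hr1G007380 from 96.0 ± 24.6 to 8.56 ± 3.33 FPKM (-3.50, SE 0.43) and HORVU4Hr1G063350 from 9.74 ± 4.10 to 0.67 ± 0.252 FPKM (-3.87, SE 0.34). The oleosin HORVU5Hr1G056030 fell again, to 8.79 ± 8.52 FPKM, and the endoglucanase HORVU5Hr1G052830 fell to 2.87 ± 0.788 FPKM. A peroxidase (HORVU4Hr1G022280) fell from 155 ± 75 to 48.6 ± 8.65 FPKM. The calls of this peroxidase and the oleosin were lost when only the compared groups were fitted, and those of the endoglucanase and the SAUR gene with a pseudocount of 5. A cysteine proteinase (HORVU3Hr1G091790) and a histone H2A (HORVU0Hr1G013190) were also taken by the naming rule, but lost their calls in 10 and 3 of 16 other settings and in 4 and 5 of 6 cases without a library. So was a lipid-transfer protein (HORVU5Hr1G046550, log2 change -1.86), whose call was lost with only the compared groups and without replicate 3 of IME at 24 h. The highest adjusted p of the other genes given here by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.013, that of the oleosin. A small subunit ribosomal RNA locus was also higher (33.7 ± 16.8 against 0.804 ± 0.229 FPKM), and the share of ribosomal RNA differed between replicates of IME at 48 h, reaching 0.791% in replicate 1.

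Camera called 12 lists between 48 h and 24 h. Glutathione S-transferases were higher, with 13 of 73 loci higher and 0 lower (20 and 0 adjusted over the list alone, median 0.65, or 0.63 at the bound, adjusted p = 2.7e-10), and this call held with an estimated correlation (adjusted p = 0.037). Every member of this list came from codes and none from the text patterns fixed beforehand. The other calls did not hold. Flavonoid and phenylpropanoid synthesis had 9 of 97 higher and 2 lower (13 and 2 adjusted over the list alone, median 0.30, adjusted p = 0.002, and 0.27 with an estimated correlation). Heat shock proteins had 10 of 63 lower and 2 higher (14 and 2 adjusted over the list alone, median -0.30, adjusted p = 7.2e-07, and 0.053 estimated). Ribosomal proteins (median -0.20, adjusted p = 2.8e-11, and 0.26 estimated) and histones (median -0.36, adjusted p = 1.2e-07, and 0.43 estimated) were lower as lists with only 3 and 1 loci called lower (3 and 0 adjusted over the list alone, where 2 ribosomal protein loci were higher). Ribosome biogenesis (median -0.22, adjusted p = 1.4e-05, and 0.27 estimated), mitosis and cyclins (median -0.15, adjusted p = 0.0053, and 0.067 estimated) and DNA replication (median -0.10, adjusted p = 0.029, and 0.40 estimated) had 0 loci called lower, also when adjusted over the list alone. Auxin early response genes had 2 of 50 higher, the same count adjusted over the list alone (median 0.38, adjusted p = 0.0071, and 0.25 estimated).

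The jasmonate list had 1 of 29 loci higher at 48 h (2 adjusted over the list alone, median 0.21, camera adjusted p = 0.021, and 0.26 with an estimated correlation). WRKY factors had 4 of 33 higher, also when adjusted over the list alone (median 0.30, adjusted p = 0.045, and 0.25 estimated), and LEA proteins 3 of 11 lower (4 adjusted over the list alone, median -0.20, or -1.40 at the bound, adjusted p = 0.021, and 0.26 estimated), while the LEA share of counts was 0.00339% ± 0.000228 at 24 h and 0.00391% ± 0.00116 at 48 h. Leaving out a single library of IME at 24 h or 48 h ended the DNA replication, jasmonate, LEA and WRKY calls in 3, 2, 1 and 4 of 6 cases. In total 536 genes were higher and 226 lower, and these counts depended on single libraries: without replicate 1 of IME at 24 h 272 genes were higher, and without replicate 3 of IME at 24 h 273 were higher and 122 lower.

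Between 48 h and 0 h the lists called were those called between 24 h and 0 h except histones, which had 13 of 120 loci higher and 10 lower (13 and 9 adjusted over the list alone, median 0.38, camera adjusted p = 0.25). None of these calls between 48 h and 0 h held with an estimated correlation. The auxin-responsive protein HORVU7Hr1G026970 reached 87.5 ± 44.5 FPKM at 48 h (log2 change from 0 h 11.75, SE 0.72), and the SAUR gene HORVU7Hr1G096870 went from 0 counts to 6.76 ± 2.73 FPKM, at least 439-fold higher. The glutathione S-transferase HORVU2Hr1G124300 was at least 701-fold higher than at 0 h, where it had 0 counts, and HORVU5Hr1G118800 went from 0 counts to 7.32 ± 1.38 FPKM, at least 531-fold higher. The peroxidase HORVU3Hr1G074920 rose from 0.00836 ± 0.0145 to 40 ± 4.89 FPKM (11.54, SE 0.71) and the endoglucanase HORVU1Hr1G085830 from 0.0375 ± 0.0106 to 43.1 ± 10.6 FPKM (9.53, SE 0.33). Proliferating cell nuclear antigen (HORVU2Hr1G088030) stayed at 123 ± 22.8 FPKM, and an H/ACA ribonucleoprotein subunit (HORVU4Hr1G047580), which guides rRNA modification, rose from 33.4 ± 3.73 to 130 ± 37.5 FPKM. Small heat shock protein HORVU4Hr1G060760 fell from 1411 ± 144 to 0.0356 ± 0.0308 FPKM (-15.62, SE 0.53). LEA protein B19.4 (HORVU1Hr1G059910) fell from 96.0 ± 47.5 to 0.15 ± 0.0764 FPKM (-9.70, SE 0.58), and a protein phosphatase 2C of the abscisic acid pathway (HORVU4Hr1G060370) from 63.1 ± 6.51 to 1.51 ± 1.53 FPKM. Beta-amylase (HORVU4Hr1G089510) fell from 44.7 ± 21.6 FPKM to 0 counts, at least 9305-fold lower, and is among the loci that rank the IME libraries at 0 h as the grain inhibitors do. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the highest adjusted p of these genes was 3e-05, that of HORVU5Hr1G118800.

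Camera called 11 lists between 48 h and 0 h, with the adjusted p at the estimated correlation given beside each. Ribosomal proteins (135 of 344 higher and 22 lower, 137 and 22 adjusted over the list alone, median 0.85, adjusted p = 1.9e-09, and 0.28 with an estimated correlation) and auxin early response genes (38 of 50 higher and 4 lower, median 2.31, adjusted p = 4.6e-06, and 0.077 estimated) were higher. Glutathione S-transferases had 42 of 73 higher and 7 lower (43 and 7 adjusted over the list alone, median 1.38, adjusted p = 7.5e-05, and 0.12 estimated) while their share of counts went from 0.882% ± 0.137 to 0.860% ± 0.0765, and peroxidases had 42 of 79 higher and 10 lower (median 1.83, adjusted p = 0.00028, and 0.20 estimated). DNA replication (median 0.72, adjusted p = 0.0019, and 0.28 estimated), ribosome biogenesis (median 0.56, or 0.57 at the bound, adjusted p = 0.003, and 0.46 estimated) and proteasome loci (median 0.32, adjusted p = 0.0031, and 0.28 estimated) were also higher. Heat shock proteins (31 of 63 lower and 10 higher, median -1.37, adjusted p = 5.4e-06, and 0.077 estimated), LEA proteins (10 of 11 lower and 1 higher, median -7.96, adjusted p = 7.5e-05, and 0.10 estimated) and abscisic acid genes (25 of 50 lower and 7 higher, median -1.03, adjusted p = 0.0053, and 0.15 estimated) were lower. The oil body list was lower (23 of 39 lower and 12 higher, median -6.25, adjusted p = 0.003, and 0.42 estimated). Without the 11 members that follow the grain inhibitors in IME at 0 h, it had 12 of 28 lower and 12 higher (median 0.09, adjusted p = 0.412), in part because that selection removes falls. Counts with no other figure beside them were identical when adjusted over the list alone. In total 4273 genes were higher and 3861 lower (52.5% higher), against 4953 and 2260 (68.7% higher) with FPKM as deposited and 6890 and 2769 (71.3% higher) with library size only.

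The comparison of ME at 24 h with 0 h asked the same of mature scutella. At the preset correlation only, the lists of histones, DNA replication, mitosis, peroxidases and ribosomal proteins were called higher and that of LEA proteins lower. Histone H2A HORVU6Hr1G021250 rose from 0.0661 ± 0.0668 to 16.9 ± 5.96 FPKM (log2 change 7.59, SE 0.49) and histone H2B HORVU4Hr1G070240 from 0.769 ± 0.305 to 114 ± 30.4 FPKM (6.94, SE 0.38). The B subunit of DNA polymerase alpha (HORVU7Hr1G102300) rose from 0.184 ± 0.0416 to 8.87 ± 1.02 FPKM (5.32, SE 0.17), and a second proliferating cell nuclear antigen (HORVU6Hr1G088120) from 0.165 ± 0.0711 to 8.32 ± 2.18 FPKM. A cell division control protein (HORVU3Hr1G084800) rose from 0.0346 ± 0.0335 to 5.77 ± 1.27 FPKM, and subunit 1 of condensin (HORVU2Hr1G022720), which compacts chromosomes, from 0.357 ± 0.0416 to 11 ± 2.58 FPKM. A DNA (cytosine-5)-methyltransferase (HORVU6Hr1G089250) rose from 0.264 ± 0.0885 to 32.0 ± 5.38 FPKM (6.64, SE 0.25), and a cytosine-specific methyltransferase (HORVU0Hr1G039040) from 3.28 ± 0.362 to 37.8 ± 6.62 FPKM. A peroxidase (HORVU4Hr1G084910) rose from 0.0107 ± 0.0185 to 22.7 ± 5.08 FPKM (10.54, SE 0.60). An annexin (HORVU1Hr1G016080) went from 0.00849 ± 0.0147 to 10.3 ± 1.45 FPKM, and a hydroxycinnamoyltransferase (HORVU1Hr1G019410) from 0.0201 ± 0.0177 to 14.7 ± 5.56 FPKM. Centroradialis (HORVU2Hr1G072750), a phosphatidylethanolamine-binding protein, rose from 0.0275 ± 0.0255 to 15.1 ± 1.90 FPKM (8.74, SE 0.44). A cysteine proteinase inhibitor (HORVU3Hr1G078680) rose from 0.109 ± 0.188 to 68.2 ± 36.4 FPKM. Aldose 1-epimerase (HORVU7Hr1G034070) rose from 3.27 ± 0.575 to 212 ± 80.4 FPKM.

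Among genes taken by the naming rule, a WAT1-related transporter (HORVU0Hr1G030660) had the largest fall in ME. It went from 13.3 ± 1.68 FPKM to 0 counts, at least 1358-fold lower. A gibberellin 3-oxidase (HORVU2Hr1G117810), of the family that makes bioactive gibberellins, fell from 58.2 ± 10.9 to 0.157 ± 0.0145 FPKM (log2 change -8.73, SE 0.32). LEA protein B19.4 (HORVU1Hr1G059910) fell from 97.8 ± 38.9 to 0.303 ± 0.193 FPKM, and the dehydrin HORVU6Hr1G084070 from 276 ± 40.4 to 1.70 ± 0.612 FPKM (-7.59, SE 0.41). A type 4 metallothionein (HORVU1Hr1G052180) fell from 313 ± 61.3 to 1.05 ± 0.189 FPKM (-8.45, SE 0.46). A WRKY33-type factor (HORVU6Hr1G028790) fell from 218 ± 22.9 to 9.65 ± 0.656 FPKM (-4.74, SE 0.20). A type-A response regulator of cytokinin signalling (HORVU2Hr1G120490) fell from 6.75 ± 2.36 to 0.401 ± 0.026 FPKM, and a type-B regulator (HORVU3Hr1G114970) from 27.7 ± 1.38 to 4.55 ± 1.12 FPKM. A 5.8S ribosomal RNA locus also fell, from 37.0 ± 5.10 to 0.000901 ± 0.000706 FPKM. Its counts gave a log2 change of -8.87, a smaller fall than these FPKM values give, for a reason that was not tested. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the highest adjusted p of the genes given here for ME was 0.00013, that of the cysteine proteinase inhibitor.

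Camera called 11 lists in ME, none of which held with an estimated correlation. Histones were higher in 105 of 120 loci and lower in 4 (105 and 5 adjusted over the list alone, median 4.39, adjusted p = 5.9e-17, and 0.38 with an estimated correlation), and went from 0.103% ± 0.0122 to 0.644% ± 0.136 of counts. DNA replication had 37 of 79 higher and 5 lower (adjusted p = 2.8e-05, and 0.23 estimated), and ribosomal proteins 113 of 344 higher and 30 lower (median 0.70, adjusted p = 3.6e-06, and 0.41 estimated). Peroxidases had 46 of 79 higher and 10 lower (median 1.85, adjusted p = 0.0021, and 0.38 estimated). LEA proteins had 10 of 11 lower and 0 higher (median -6.47, adjusted p = 0.00018, and 0.23 estimated), and WRKY factors 14 of 33 lower and 4 higher (median -0.73, adjusted p = 0.017, and 0.23 estimated). Calls closer to the threshold were DNA methylation and Polycomb (23 of 69 higher and 7 lower, median 0.61, adjusted p = 0.038, and 0.41 estimated) and mitosis and cyclins (17 of 42 higher and 3 lower, median 0.60, adjusted p = 0.040, and 0.23 estimated). Mitosis and cyclins went from 0.166% ± 0.0207 to 0.153% ± 0.00978 of counts, and DNA replication from 0.184% ± 0.00665 to 0.408% ± 0.0355. The share of glycolysis and fermentation, a list called higher, went from 4.24% ± 0.291 to 3.81% ± 0.278. Glycolysis and fermentation (70 of 170 higher and 39 lower, median 0.69, 0.43 estimated), proteasome (23 of 103 higher and 9 lower, median 0.29, 0.41 estimated) and cytokinin (18 of 36 lower and 6 higher, median -1.06, or -1.12 at the bound, 0.41 estimated) each had an adjusted p of 0.040. Each of these 5 calls was lost under at least 1 other scaling, and the last 3 also without replicate 2 of ME at 24 h. Counts with no other figure beside them were identical when adjusted over the list alone. In total 5373 genes were higher and 5191 lower.

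**Figure D4:**
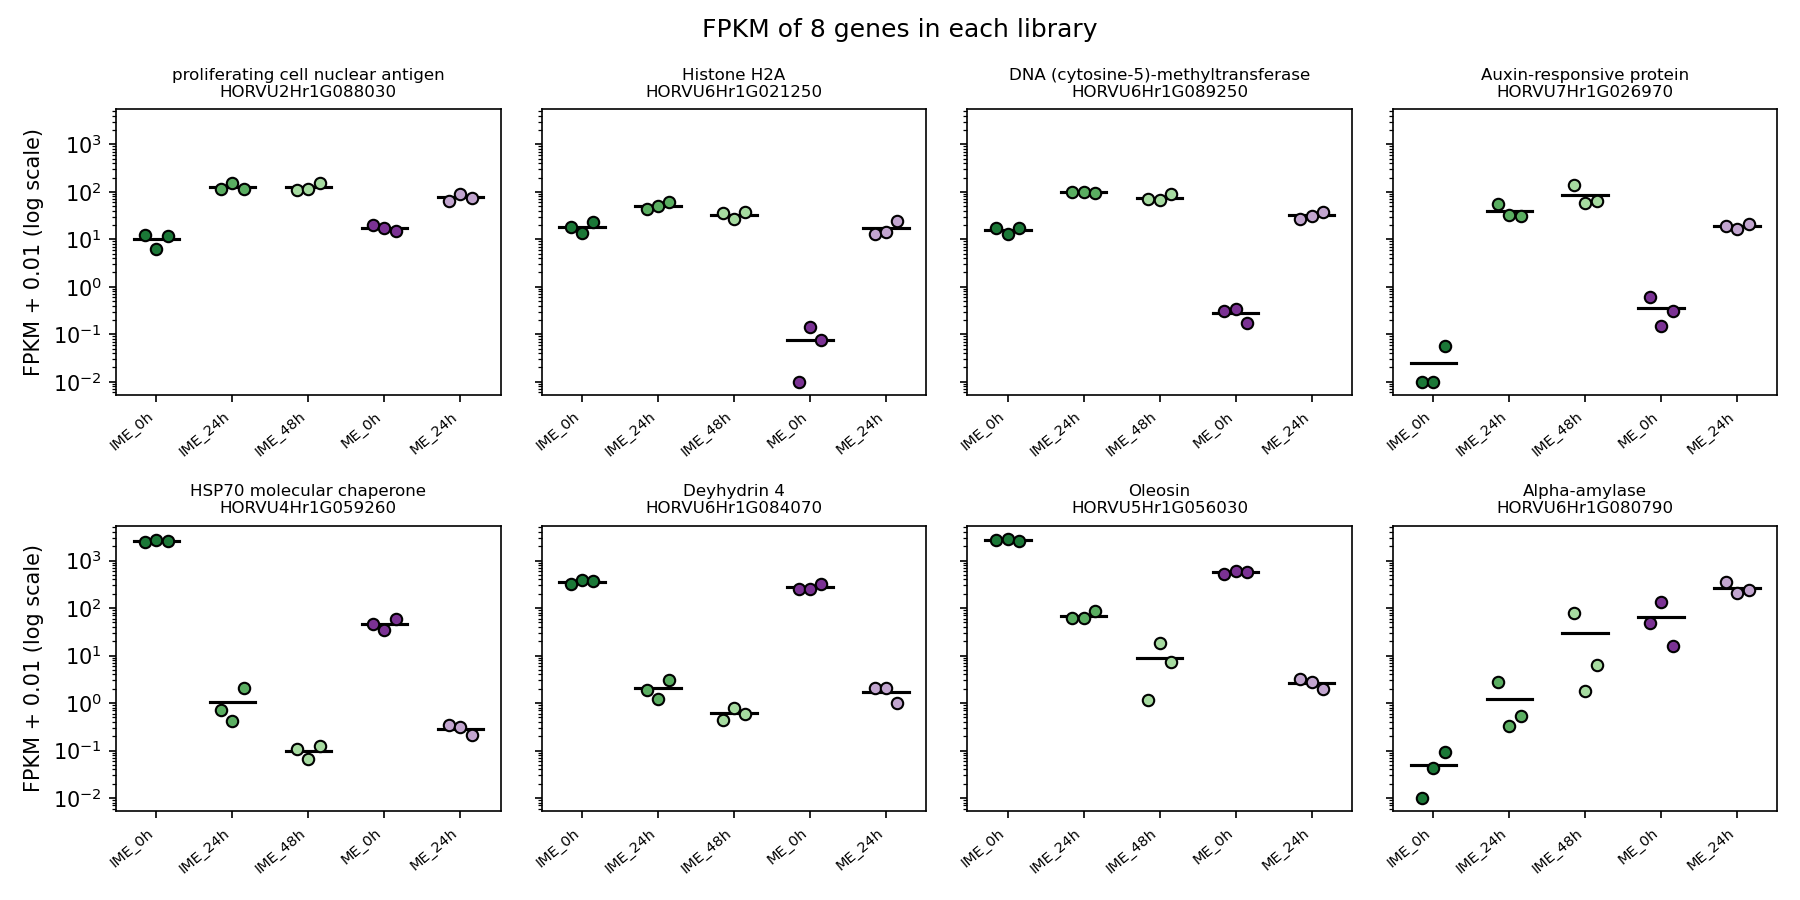
FPKM + 0.01 of 8 genes on a log scale (y axis) in the 5 groups (x axis); points are libraries and lines are group means. Histone H2A HORVU6Hr1G021250 is at 18.2 ± 4.57 FPKM in IME and 0.0661 ± 0.0668 FPKM in ME at 0 h, and at 50.7 ± 8.46 and 16.9 ± 5.96 FPKM at 24 h.

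Changes were shared between embryo types more often than independent lists would give. The comparisons have no library in common, but both came from a single fit that shares each gene's estimate of spread. A gene of low spread is thus easier to call in both, which the expected counts leave out. Of the 20858 genes, 2189 were higher at 24 h in both types (1063 expected of independent lists) and 2311 lower in both (1027 expected). Over 17 other settings the shared counts ran from 1052 to 4456 higher and from 559 to 4021 lower. Another 406 rose in IME and fell in ME (1027 expected), and 340 did the reverse (1063 expected). The log2 changes correlated across genes at Pearson's r = 0.53 and Spearman's rho = 0.49, over genes that are not independent. LEA proteins were called lower in both types, and histones, DNA replication, ribosomal proteins, peroxidases and proteasome were called higher in both, at the preset correlation. With an estimated correlation none of these 6 lists was called in either type, and the proteasome call in IME came with 14 loci higher and 11 lower of 103.

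The interaction asked which genes responded differently to 24 h of culture. It set the change in IME against the change in ME, and a positive value is a higher change in IME. An inositol-tetrakisphosphate 1-kinase (HORVU7Hr1G033170) rose in IME from 0.00982 ± 0.017 to 2.33 ± 0.250 FPKM and fell in ME from 19.4 ± 3.75 to 4.33 ± 0.949 FPKM (difference of log2 changes 9.64, SE 0.71). An abscisic acid receptor of the PYR/PYL family (HORVU7Hr1G088140) rose in IME from 0.559 ± 0.190 to 13.1 ± 1.80 FPKM and fell in ME from 27.2 ± 5.08 to 2.32 ± 0.492 FPKM (7.87, SE 0.39). A serine/threonine protein kinase (HORVU4Hr1G021090) had 18.6 ± 2.10 FPKM in ME at 0 h and at most 0.332 ± 0.0882 FPKM in the other groups (9.10, SE 0.99). A peroxidase (HORVU5Hr1G046900) rose in IME from 0.0426 ± 0.0489 to 36.1 ± 1.99 FPKM and in ME from 10.5 ± 1.16 to 29.7 ± 4.31 FPKM (7.89, SE 0.59). A ribosome biogenesis regulatory protein (HORVU6Hr1G014750) rose in IME from 21.5 ± 3.67 to 73.3 ± 4.29 FPKM and was not called in ME, at 56.1 ± 3.13 and 49.8 ± 4.59 FPKM (1.73, SE 0.17). The CMF6b fragment HORVU1Hr1G095390, of the ribosome biogenesis list, was 33.2 ± 3.89 FPKM in ME at 0 h and fell to 9.77 ± 0.543 FPKM (2.56, SE 0.28).

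Negative differences included the small heat shock protein HORVU3Hr1G006530, which fell in IME from 490 ± 41.7 to 0.311 ± 0.317 FPKM and had 0.931 ± 0.584 FPKM in ME at 0 h (difference of log2 changes -9.05, SE 0.90). Another small heat shock protein, HORVU6Hr1G015130, rose in ME from 0.0172 ± 0.0298 to 9.77 ± 4.75 FPKM and was not called in IME (-9.48, SE 1.32). The DNA (cytosine-5)-methyltransferase HORVU6Hr1G089250 rose in IME from 15.9 ± 2.63 to 96.7 ± 2.46 FPKM, and rose more steeply in ME from its low start (-4.51, SE 0.29). The same held for the histone H2A HORVU6Hr1G021250 (-6.58, SE 0.60). An RNA-dependent RNA polymerase (HORVU3Hr1G027340) fell in IME from 5.18 ± 0.278 to 0.922 ± 0.0517 FPKM and rose in ME only within values under 0.1 FPKM (-4.08, SE 0.51). A flavonol synthase (HORVU6Hr1G088470) fell in IME from 13.6 ± 3.62 to 0.0913 ± 0.105 FPKM (-8.29, SE 1.22). The grain inhibitor CMd (HORVU4Hr1G081640) fell in IME from 74.4 ± 48.0 to 0.0634 ± 0.110 FPKM (-11.46). The naming rule also took trypsin inhibitor CMe (HORVU3Hr1G012970, -8.33, SE 3.08), histone H2A HORVU1Hr1G071950 (-8.34, SE 1.77), the NAC factor HORVU4Hr1G017430 (-1.17, SE 0.22), ribosomal protein S12 HORVU3Hr1G004730 (3.80, SE 1.07), rps13 (3.24, SE 0.53) and glutathione S-transferase HORVU2Hr1G052920 (8.56, SE 1.69). Without replicate 1 of IME at 0 h the S12 value was 11.03, and this glutathione S-transferase is near 0 in replicate 3 of ME at 24 h alone among that group. The calls of the methyltransferase, the RNA polymerase and histone H2A HORVU6Hr1G021250 were lost with a pseudocount of 5, and that of the NAC factor in 5 of 16 other settings. CMe lost its call in 1 of 15 other settings and in 2 of 12 cases without a library. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the highest adjusted p of the genes named for the interaction was 0.030, that of CMe.

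Camera called 5 lists in the interaction, none of which held with an estimated correlation. Histones had 96 of 120 loci with a lower change in IME and 1 with a higher one (median difference -3.65, adjusted p = 1.5e-15, and 0.36 with an estimated correlation). Heat shock proteins had 38 of 63 lower and 7 higher (38 and 8 adjusted over the list alone, median -2.59, adjusted p = 6.6e-06, and 0.16 estimated). Ribosome biogenesis had 54 of 121 higher and 9 lower (54 and 10 adjusted over the list alone, median 0.87, adjusted p = 2.8e-07, and 0.36 estimated). Ribosomal proteins had 56 of 344 higher and 37 lower (median 0.44, adjusted p = 0.0095, and 0.72 estimated). DNA methylation and Polycomb had 27 of 69 lower and 6 higher (28 and 6 adjusted over the list alone, median -0.66, adjusted p = 0.016, and 0.36 estimated), a call lost under 2 other scalings, with adjusted p up to 0.119. Histone and ribosomal protein counts were identical when adjusted over the list alone. In total 4085 genes had a higher and 4720 a lower change in IME (46.4% higher), against 4198 and 3186 (56.9% higher) with FPKM as deposited and 5176 and 3782 (57.8% higher) with library size only. Splits of the libraries that mixed groups called as many lists or more, up to 15, so the number of lists called carries little weight.

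Before culture, the lists of histones, DNA replication, heat shock proteins and oil bodies were called higher in IME and those of glutathione S-transferases, cytokinin and ethylene lower, at the preset correlation only. The summed share of glutathione S-transferases did not follow its list, with 0.882% ± 0.137 of counts in IME and 0.838% ± 0.0357 in ME. Histone H4 HORVU1Hr1G073680 was 19.5 ± 5.29 FPKM in IME and 0.0962 ± 0.0866 FPKM in ME (log2 difference 7.61, SE 0.53). A replication protein A subunit (HORVU4Hr1G067940), which binds single-stranded DNA, was 8.60 ± 0.759 against 0.385 ± 0.115 FPKM (4.50, SE 0.21), and DNA primase (HORVU1Hr1G059180) 8.79 ± 0.790 against 0.56 ± 0.138 FPKM. The kinesin-like protein HORVU1Hr1G072370 was 7.47 ± 1.45 against 0.308 ± 0.0631 FPKM (4.59, SE 0.19). A small heat shock protein (HORVU2Hr1G120170) was 605 ± 54.9 against 0.426 ± 0.329 FPKM (10.48, SE 0.63). The oleosin HORVU4Hr1G005800 was 2809 ± 100 against 184 ± 44.1 FPKM (3.96, SE 0.43), and HORVU5Hr1G056030 was 2741 ± 139 against 569 ± 51.0 FPKM (2.29, SE 0.58), a call lost with quantile normalization. The alpha-amylase inhibitor BMAI-1 (HORVU2Hr1G122260) was 43.0 ± 30.4 FPKM against 0 counts, at least 2788-fold higher, and trypsin inhibitor CMe (HORVU3Hr1G012970) was 63.5 ± 55.1 against 0.094 ± 0.0999 FPKM.

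Higher in ME at 0 h was a glutathione S-transferase (HORVU3Hr1G117370) with 826 ± 139 FPKM, against 0.872 ± 0.598 FPKM in IME (log2 difference -9.85, SE 0.67). Another (HORVU2Hr1G052920) had 204 ± 13.6 FPKM, against 0.162 ± 0.0715 FPKM, and is among loci near 0 in a single library of another group. An alpha-amylase (HORVU6Hr1G080790), which breaks down starch, had 65.0 ± 59.8 FPKM in ME and 0.0389 ± 0.0419 FPKM in IME (-10.54, SE 1.92). The WAT1-related protein HORVU6Hr1G080260 had 66.7 ± 21.7 against 0.137 ± 0.0415 FPKM. Response regulators of cytokinin signalling were higher in ME, HORVU7Hr1G030050 at 27.1 ± 3.72 against 0.245 ± 0.0421 FPKM (-6.74, SE 0.26) and the type-B regulator HORVU7Hr1G030020 at 33.8 ± 8.08 against 0.31 ± 0.0746 FPKM. A 1-aminocyclopropane-1-carboxylate oxidase (HORVU5Hr1G065620), which makes ethylene, was 23.8 ± 5.15 against 1.21 ± 0.103 FPKM (-4.25, SE 0.21). A WRKY2-type factor (HORVU5Hr1G072020) was 17.3 ± 2.23 against 2.03 ± 0.212 FPKM, and mitochondrial rps13 was 17.4 ± 2.29 against 1.15 ± 0.287 FPKM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the highest adjusted p of the genes named for 0 h was 0.036, that of the HSP70 chaperone HORVU5Hr1G021310 (9.94, SE 3.94), whose call was lost in 8 of 15 other settings and in 4 of 6 cases without a library, and whose value was 2.33 without replicate 1 of IME at 0 h. The next was 0.0082, that of CI-1A (HORVU1Hr1G012130), which had 0 counts in ME at 0 h and was at least 229-fold higher in IME.

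Among the immature libraries at 0 h, grain inhibitors differed widely. The 8 inhibitor loci picked by name were all lowest in replicate 2 and highest in replicate 3. Leaving aside the Bowman-Birk type trypsin inhibitor HORVU3Hr1G004140, which spread by 1.18-fold, the other 7 summed to 180.2, 77.4 and 386.2 FPKM in replicates 1, 2 and 3, a spread of 4.99-fold. The oil body list summed to 40520.0, 38730.0 and 40560.0 FPKM in the same libraries. Of the 48 tested loci in the grain inhibitor list, 14 were read in IME at 0 h alone and spread in the inhibitor order. The other 34 had 7 loci higher and 14 lower in IME than in ME at 0 h (median log2 difference -1.78).

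**Figure D5:**
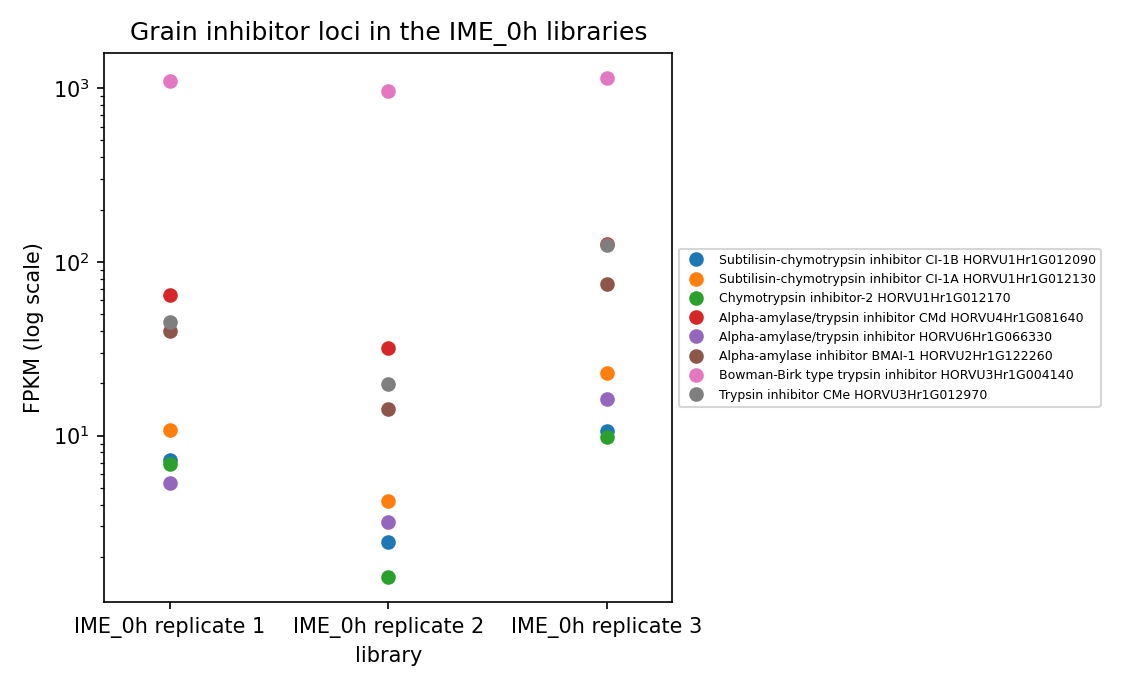
FPKM on a log scale (y axis) of 8 amylase and protease inhibitor loci picked by name, in the 3 IME libraries at 0 h (x axis). Each point is a locus in a library, coloured by locus. Replicate 2 is lowest and replicate 3 highest at each locus, with spreads of 1.18-fold to 6.42-fold.

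Camera called 12 lists between IME and ME at 0 h, none of which held with an estimated correlation. Histones were higher in IME in 106 of 120 loci and lower in 1 (108 and 1 adjusted over the list alone, median 4.68, adjusted p = 9.3e-18, and 0.31 with an estimated correlation). Heat shock proteins had 42 of 63 higher and 9 lower (median 2.93, adjusted p = 5.2e-06, and 0.070 estimated). DNA replication (37 of 79 higher and 4 lower, median 1.04, adjusted p = 0.00011, and 0.20 estimated), DNA methylation and Polycomb (34 of 69 higher and 3 lower, median 1.07, adjusted p = 0.00011, and 0.20 estimated) and mitosis and cyclins (21 of 42 higher and 2 lower, median 1.05, adjusted p = 0.00081, and 0.070 estimated) were higher. The share of counts of mitosis and cyclins went the other way, with 0.135% ± 0.00444 in IME and 0.166% ± 0.0207 in ME. The oil body list had 25 of 39 higher and 6 lower (median 3.81, or 3.87 at the bound, adjusted p = 0.022, and 0.54 estimated). Without the 11 members that follow the grain inhibitors between the IME libraries, it had 14 of 28 higher and 6 lower (median 1.03, adjusted p = 0.55), in part because that selection removes differences. Ribosome biogenesis was lower in IME (44 of 121 lower and 13 higher, median -0.60, adjusted p = 0.00088, and 0.53 estimated). Lower in IME with an adjusted p of 0.022 were cytokinin (14 of 36 lower and 6 higher, median -0.93, or -0.86 at the bound, 0.31 estimated), ethylene (14 of 22 lower and 2 higher, median -1.94, 0.20 estimated), WRKY (18 of 33 lower and 6 higher, median -1.72, 0.20 estimated) and glutathione S-transferases (34 of 73 lower and 17 higher, median -1.11, 0.37 estimated). Ribosomal proteins had 44 of 344 lower and 43 higher (median -0.32, adjusted p = 0.046, and 0.82 estimated), a call lost under 4 other scalings and in 3 of 6 cases without a library, and the WRKY call was lost under 3 scalings. Counts with no other figure beside them were identical when adjusted over the list alone. In total 5620 genes were higher and 5007 lower in IME.

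After 24 h of culture the embryo types were closer. The lists of mitosis, histones and DNA replication were called higher in IME and those of glycolysis and of flavonoid and phenylpropanoid synthesis lower, and of these only mitosis held with an estimated correlation. Called genes numbered 10627 at 0 h and 4212 at 24 h, and the SD of the log2 differences over genes went from 2.66 to 1.48. At both times 2619 genes were called with the same sign and 425 with opposite signs. Independent lists would give 1066 with the same sign, though both comparisons came from a single fit that shares each gene's estimate of spread. Kinesin-like protein HORVU3Hr1G052930 was 16.2 ± 0.550 FPKM in IME and 1.98 ± 0.456 FPKM in ME (log2 difference 2.83, SE 0.28), and HORVU1Hr1G072370 was 23.9 ± 2.06 against 3.16 ± 0.243 FPKM (2.71, SE 0.16). Histone H2A HORVU6Hr1G011490 was 32.4 ± 5.55 against 4.13 ± 1.95 FPKM, and flap endonuclease 1 (HORVU1Hr1G079900), which trims replicated strands, 42.5 ± 3.02 against 12.3 ± 0.967 FPKM (1.59, SE 0.09). A histone-lysine methyltransferase (HORVU7Hr1G026840) was 13.2 ± 0.509 against 4.21 ± 0.486 FPKM, a call lost with a pseudocount of 5. The oleosin HORVU4Hr1G005800 was 159 ± 47.0 against 0.831 ± 0.150 FPKM (7.37, SE 0.53), the Bowman-Birk inhibitor HORVU3Hr1G004140 was 153 ± 36.8 against 2.48 ± 3.25 FPKM, and the starch synthase HORVU7Hr1G012380 was 67.4 ± 1.08 against 1.29 ± 0.0936 FPKM. A YUCCA-type monooxygenase (HORVU0Hr1G012990), of the family that makes auxin, was 12 ± 2.46 against 0.398 ± 0.0759 FPKM (4.71, SE 0.24). The lipid-transfer protein HORVU5Hr1G046520 was 294 ± 39.6 against 10.5 ± 7.14 FPKM.

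Higher in ME at 24 h were alpha-amylases, HORVU6Hr1G078420 with 61.7 ± 20.8 FPKM against 0 counts (at least 7307-fold lower in IME) and HORVU0Hr1G032850 with 27.6 ± 16.1 against 0.0678 ± 0.117 FPKM. A phenylalanine ammonia-lyase (HORVU6Hr1G058840), the entry to phenylpropanoids, was 12.8 ± 1.64 in ME against 0.165 ± 0.0829 FPKM in IME (log2 difference -6.44, SE 0.47). A sulfotransferase (HORVU2Hr1G008960) was 12.9 ± 1.20 against 0.0696 ± 0.0271 FPKM (-7.62, SE 0.27), and a xyloglucan endotransglucosylase/hydrolase (HORVU7Hr1G098370) was 12.5 ± 6.86 against 0.122 ± 0.211 FPKM. Aldose 1-epimerase (HORVU7Hr1G034070) was 212 ± 80.4 against 15.6 ± 5.16 FPKM (-3.96, SE 0.31), and a phosphotransferase of the glycolysis list (HORVU3Hr1G070690) was 238 ± 39.5 against 22.0 ± 3.16 FPKM. The jasmonate gene 12-oxophytodienoate reductase (HORVU7Hr1G036070) was 79.7 ± 7.12 against 21.3 ± 1.86 FPKM (-2.10, SE 0.20). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the highest adjusted p of the genes given here for 24 h was 0.00087, that of the alpha-amylase HORVU6Hr1G078420.

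Camera called 11 lists between IME and ME at 24 h. Mitosis and cyclins were higher in IME (15 of 42 higher and 1 lower, median 0.63, adjusted p = 3e-06), the single call that held with an estimated correlation (adjusted p = 0.0080). Histones (41 of 120 higher and 2 lower, median 0.84, adjusted p = 6.9e-08, and 0.42 with an estimated correlation), DNA methylation and Polycomb (14 of 69 higher and 1 lower, 15 and 1 adjusted over the list alone, median 0.39, adjusted p = 3.5e-06, and 0.10 estimated) and DNA replication (8 of 79 higher and 2 lower, median 0.51, adjusted p = 4.7e-05, and 0.26 estimated) were higher. Ribosome biogenesis (7 of 121 higher and 2 lower, median 0.34, adjusted p = 0.0004, and 0.42 estimated) and heat shock proteins (18 of 63 higher and 9 lower, 19 and 9 adjusted over the list alone, median 0.56, adjusted p = 0.030, and 0.36 estimated) were also higher. Flavonoid and phenylpropanoid synthesis was lower (43 of 97 lower and 13 higher, median -0.89, adjusted p = 0.0003, and 0.36 estimated), as were cellulose synthases (7 of 17 lower and 3 higher, median -0.81, adjusted p = 0.010, and 0.10 estimated) and glycolysis and fermentation (33 of 170 lower and 14 higher, median -0.27, adjusted p = 0.010, and 0.36 estimated). Glutathione S-transferases (18 of 73 lower and 5 higher, median -0.53, adjusted p = 0.033, and 0.36 estimated) and jasmonate genes (10 of 29 lower and 3 higher, 11 and 3 adjusted over the list alone, median -0.75, or -0.73 at the bound, adjusted p = 0.035, and 0.36 estimated) were lower. Heat shock proteins lost the call under 4 scalings and without replicate 3 of IME at 24 h, and the last 2 lists each lost it in 2 of 6 cases without a library. Counts with no other figure beside them were identical when adjusted over the list alone. In total 1851 genes were higher and 2361 lower in IME (43.9% higher), against 2533 and 1896 (57.2% higher) with library size only.

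Of the tested lists, 11 were called in no comparison. Between IME at 24 h and 0 h, auxin response factors had 11 of 30 loci higher and 3 lower (11 and 4 adjusted over the list alone, median 0.28), auxin transport and synthesis 9 of 23 higher and 2 lower (median 0.43), and gibberellin 12 of 43 higher and 15 lower (median -0.44). In the same comparison cell wall remodelling had 23 of 68 higher and 15 lower (median 0.44), pathogenesis-related proteins 13 of 49 higher and 1 lower (median 0.11), and bHLH factors 4 of 23 higher and 8 lower (median -0.71, with a mean of 0.13). Photosynthesis had 8 of 51 higher and 21 lower (median -0.45), starch and amylases 8 of 58 higher and 16 lower (median -0.10), the glyoxylate cycle and beta-oxidation 2 of 30 higher and 4 lower (median -0.12), and sugar and amino acid transporters 1 of 6 higher and 3 lower (median -0.86). Grain inhibitors had 13 of 48 higher and 25 lower (median -1.62), and were called higher at 48 h against 24 h only without the 14 loci of theirs that follow the pattern in IME at 0 h (6 of 34 higher and 0 lower, median 0.58, camera adjusted p = 0.0152, and 0.413 with an estimated correlation). Counts with no other figure beside them were identical when adjusted over the list alone. Median, mean and test differed in sign only in lists that were not called. In IME at 24 h against 0 h these were ethylene, jasmonate, WRKY, bHLH and glycolysis, and in ME they were auxin response factors, heat shock proteins and the glyoxylate cycle. At 48 h against 24 h they were auxin response factors, oil bodies, photosynthesis, peroxidases, cell wall, starch, proteasome and sugar transporters, and at 48 h against 0 h gibberellin, bHLH, glyoxylate cycle and flavonoids. Between the types they were bHLH, cellulose synthases, starch and flavonoids at 0 h and auxin early response, cytokinin and peroxidases at 24 h. In the interaction they were auxin transport, gibberellin, jasmonate, LEA, bHLH, pathogenesis-related proteins and proteasome.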

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

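Each gene below changed differently in IME and ME over 24 h by the interaction test, and each list was called in it at the preset correlation only. Each value is the log2 change in IME minus that in ME. The tests of embryo stage and of heat or handling were written after results had been seen. The 56 genes had adjusted p up to 0.034 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

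By the sign of the difference alone, it was positive for an auxin-responsive protein (HORVU7Hr1G026970, 5.16), a SAUR protein (HORVU7Hr1G075080, 5.61), an rRNA N-glycosidase (HORVU4Hr1G087400, 4.46), peroxidases HORVU2Hr1G018480 (6.21), HORVU5Hr1G046900 (7.89) and HORVU3Hr1G074920 (4.33), and glutathione S-transferases HORVU5Hr1G006330 (6.78), HORVU1Hr1G021140 (4.10) and HORVU2Hr1G052920 (8.56). It was also positive for the proliferating cell nuclear antigen HORVU2Hr1G088030 (1.29), 40S ribosomal protein S12 (HORVU2Hr1G053290, 1.09), ribosomal protein S12 (HORVU3Hr1G004730, 3.80), rps13 (3.24), the snoR60 locus (HORVU6Hr1G091860, 1.59), the 5.8S ribosomal RNA locus (7.60), RNA cytidine acetyltransferase (HORVU4Hr1G071270, 1.05), a proteasome beta subunit (HORVU5Hr1G076130, 1.01) and a ribosome biogenesis regulator (HORVU6Hr1G014750, 1.73). Further positive values belonged to oleosins HORVU5Hr1G056030 (2.23) and HORVU4Hr1G005800 (3.41), a WAT1-related protein (HORVU0Hr1G030660, 6.62 as fitted over 0 counts in ME at 24 h, and at least 3.70 at the bound), gibberellin 3-oxidase (HORVU2Hr1G117810, 7.29), a type-A response regulator (HORVU2Hr1G120490, 4.09), a WRKY33-type factor (HORVU3Hr1G088200, 1.23) and CMF6b (HORVU1Hr1G095390, 2.56). The kinases HORVU7Hr1G033170 (inositol-tetrakisphosphate 1-kinase, 9.64) and HORVU4Hr1G021090 (serine/threonine kinase, 9.10) and a PYR/PYL receptor (HORVU7Hr1G088140, 7.87) complete this group.

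Negative values belonged to HSP70 (HORVU4Hr1G059260, -4.08), small heat shock proteins HORVU3Hr1G006530 (-9.05) and HORVU6Hr1G015130 (-9.48), glutamate decarboxylase (HORVU3Hr1G112860, -6.82), a hexosyltransferase (HORVU4Hr1G052450, -4.40), an ABRE-binding bZIP factor (HORVU3Hr1G083250, -4.79), abscisic acid 8'-hydroxylase (HORVU5Hr1G068330, -2.70), a NAC factor (HORVU4Hr1G017430, -1.17), metallothionein type 4 (HORVU1Hr1G052180, -2.51), CMd (HORVU4Hr1G081640, -11.46), CMe (HORVU3Hr1G012970, -8.33), a flavonol synthase (HORVU6Hr1G088470, -8.29) and RNA-dependent RNA polymerase (HORVU3Hr1G027340, -4.08). The CMe call was lost without the expression filter and without replicate 2 or 3 of ME at 24 h. Histones H2A HORVU7Hr1G100400 (-2.98), HORVU6Hr1G021250 (-6.58) and HORVU1Hr1G071950 (-8.34) and H2B HORVU4Hr1G073130 (-2.03) and HORVU4Hr1G070240 (-5.56) had negative values too. So did DNA polymerase alpha subunit B (HORVU7Hr1G102300, -3.69), a proliferating cell nuclear antigen (HORVU6Hr1G088120, -3.81), a cell division control protein (HORVU3Hr1G084800, -3.29), condensin subunit 1 (HORVU2Hr1G022720, -2.94), methyltransferases HORVU6Hr1G089250 (-4.51) and HORVU0Hr1G039040 (-1.39), a peroxidase (HORVU7Hr1G045600, -2.28), aldose 1-epimerase (HORVU7Hr1G034070, -4.73), fructose-bisphosphate aldolase (HORVU5Hr1G032980, -1.91) and a proteasome endopeptidase (HORVU2Hr1G036390, -1.21). Lists called at the preset correlation, none of which held with an estimated correlation, were histones (median -3.65), heat shock proteins (-2.59), DNA methylation and Polycomb (-0.66), ribosome biogenesis (0.87) and ribosomal proteins (0.44).

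Grain inhibitors in IME at 0 h could come from endosperm RNA left on the scutella in differing amounts. The 8 loci picked by name all ranked the 3 libraries in the same order, as that explanation predicts, though 1 spread by only 1.18-fold. So did 42 of the other 50 loci read in IME at 0 h alone with a spread of at least 2-fold. By chance 8.33 would, if loci were independent. An embryo stage differing between these libraries was predicted to move the oil body list, whose summed FPKM spread by only 1.05-fold. Yet 11 of its members spread by 4.54-fold to 6.21-fold in the inhibitor order, so this sum cannot exclude a stage difference. Hordeins could not be used as a marker, since no description in the table names them. Of all 49 loci with that spread and order, inhibitors included, 11 carried the nutrient reservoir term, which 69 loci in the table have. This term does not name a tissue, so endosperm RNA is kept as an explanation and not shown. Lists tested without the loci in that order lose members that track the inhibitors, but also lose differences by construction, since those loci were chosen for being read in IME at 0 h alone.

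Heat shock transcripts in IME at 0 h were not produced by scaling to a few abundant loci. Over 6 other scalings, and without the 10 most abundant loci of each library, the median log2 difference from ME at 0 h was at least 2.52, against 2.93. Heat or handling of the grain before sampling and seed maturation would both raise such genes, and the 42 loci called higher cannot tell them apart.

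Some abundant loci were near 0 in a single library of a group and high in its other libraries, in 313 cases over 232 loci. Reads given to a neighbouring locus were looked for as a neighbour at least 4 times higher in the low library. Of the 281 cases testable for it, 5.69% had such a neighbour (1.03% of comparison loci). Smaller gains, and neighbours not named by the assembler, would be missed, so this share does not bound that explanation. Another copy of the family gained in 3.51% of the 57 cases with a KEGG orthology entry (2.63% of comparison loci), so most cases could not be tested for a copy. Any locus whose entry no other locus shares was counted as no gain, so this share does not bound that explanation either. No library held more than 8.97% of the 312 cases not seen before that test. The cases recurred at particular loci, since 61 were low in at least 2 groups, where 2.21 would be if groups were independent. No biological explanation was tested, and the cause stays open, with 91 of these loci called in some comparison.

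Regrouping the libraries tested whether groups drawn at random could give the counts. Comparisons of 3 against 3 allow 10 splits, too few to exclude chance, and the real split was the only one (1 of 10) to reach its gene count in each of 6 comparisons. Every other split mixed libraries of both groups, so their low gene counts were set in part beforehand. The real counts were 8251, 762, 8134, 10564, 10627 and 4212, and the highest others 1, 8, 1, 2, 1 and 1. For lists, 4, 1, 4, 2, 1 and 1 of 10 splits reached the real counts of 12, 12, 11, 11, 12 and 11, and the highest others were 12, 10, 14, 12, 9 and 10. In the interaction 2 of 100 draws, the real grouping among them, reached the real gene count of 8805 (highest other 12815). The 5 lists were reached in 91 of 100. These draws mixed groups that differ strongly, so they still hold real differences. Whether chance accounts for that number of lists was therefore neither shown nor excluded.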

How the results depend on the processing

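Of 4267 values of named genes under other settings, 4177 kept direction and call, 90 kept direction but lost the call, and 0 reversed. Of the 1254 values among these with a library left out, 1235 kept the call. Every other gene count stayed within 1.5 times of its main value. For the values below the cause was not tested, except where fewer genes, a wider call or no TMM factors is the setting itself. With 3 libraries a group, simulated counts gave calls for 26% of genes changed 2-fold between IME at 24 h and 0 h. By adjusted p alone, without the limit on the change, 39% were recovered. Genes not called are therefore not shown to be unchanged.

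The main counts, higher and lower, were 4125 and 4126 (IME 24 h against 0 h), 536 and 226 (48 h against 24 h), 4273 and 3861 (48 h against 0 h), 5373 and 5191 (ME), 5620 and 5007 (IME against ME at 0 h), 1851 and 2361 (at 24 h), 4085 and 4720 (interaction), and 2189 and 2311 (both types). In that order, limma on log2(FPKM + 5) gave 2258 and 1478, 110 and 56, 2355 and 1449, 2309 and 2035, 1934 and 2236, 523 and 591, 2295 and 1760, and 1052 and 559. With a pseudocount of 0.1, IME at 24 h had 6371 higher, at 48 h 6666, and both types 3416. Adjusted p alone gave 7184 and 6799, 942 and 472, 7430 and 6531 within IME, 4859 and 4932 at 24 h between types, and 4456 and 4021 in both types.

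FPKM by median of ratios gave 2709 higher (24 h against 0 h), 247 and 134 (48 h against 24 h), 2742 higher (48 h against 0 h), 963 higher (IME against ME at 24 h) and 1277 higher in both types. FPKM by TMM gave 2738 higher, 255 and 133, 2806 higher, 1004 and 1560, and 1302 and 1525. Quantile normalization gave 264 higher (48 h against 24 h), 1130 and 1467 (IME against ME at 24 h) and 1342 lower in both. Library size only gave 6472, 6890 and 3396 higher (24 h and 48 h against 0 h, both types). FPKM as deposited in limma gave 2352 lower, 288 and 144, 2260 lower within IME, 1255 lower at 24 h between types and 1100 lower in both. Limma without trend and robust gave 2356 lower, 293 and 148, 2266 lower, 1264 lower and 1101 lower. A filter of 5 FPKM, with fewer genes tested, gave 2743 lower (24 h against 0 h), 304 higher (48 h against 24 h), 3645 higher (IME against ME at 0 h), and 1185 and 1524 (at 24 h). Only the groups compared gave 313 and 120 (48 h against 24 h).

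Lists called numbered 12, 12, 11, 11, 12, 11 and 5, and 0, 1, 0, 0, 0, 1 and 0 with an estimated correlation. Description patterns alone gave 5 (48 h against 24 h), 7 (ME), 7 (IME against ME at 0 h) and 11 (interaction). That setting tested fewer lists, since those with under 5 members by description, such as heat shock proteins and glutathione S-transferases, were left out. FPKM by median of ratios gave 6 in ME, and the interaction had 8 with FPKM as deposited and 8 with members above the median count. Without replicate 2 of ME at 0 h the interaction called 8 lists, and without replicate 1 of ME at 24 h 10. Between IME at 48 h and 24 h, 272 genes were higher without replicate 1 of IME at 24 h, and 273 higher and 122 lower without its replicate 3, against 569 higher without replicate 1 of IME at 48 h and 246 lower without its replicate 2.

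A replicate block on the libraries' numbers gave 4127 and 4115, 478 and 212, 4239 and 3854, 5368 and 5157, 5629 and 5003, 1840 and 2343, 4052 and 4720, and 2190 and 2300, with 12, 12, 11, 11, 12, 11 and 5 lists. The labels do not say that equal numbers were paired. Residuals of libraries with equal numbers correlated at 0.00351 on average, against -0.00175 for unequal numbers, and 0 of 10 pairs of groups had all such correlations over 0.1.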

Other observations

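The alpha-amylase HORVU6Hr1G080790 reached 265 ± 76.4 FPKM in ME at 24 h and 29.2 ± 43.4 FPKM in IME at 48 h (n = 3 libraries each), the latter with a wide spread. The ACC oxidase HORVU5Hr1G065620 went through 1.21 ± 0.103, 84.5 ± 10.9 and 149 ± 28.3 FPKM in IME before culture and after 24 h and 48 h of it. The YUCCA-type gene HORVU0Hr1G012990 went from 63.8 ± 9.41 to 8.97 ± 1.44 FPKM over the same 48 h, and was 0.271 ± 0.0747 FPKM in ME at 0 h. Centroradialis (HORVU2Hr1G072750) was 0.751 ± 0.0711 FPKM in IME at 24 h, against 15.1 ± 1.90 FPKM in ME.

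Among 659 KEGG and Gene Ontology terms tested in each comparison, 0 were called with an estimated correlation. At the preset correlation, auxin-activated signaling had 34 of 50 genes higher and 2 lower between IME at 24 h and 0 h (median log2 change 1.55, camera adjusted p = 2.3e-05, and 0.175 with an estimated correlation). Microtubule motor activity had 34 of 59 genes higher and 1 lower in IME than in ME at 24 h (median 1.12, camera adjusted p = 1.8e-13, and 0.234 with an estimated correlation).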
